A study of Homo sapiens with 12 samples.

How the data were processed

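RNA was measured in 12 samples of hepatocyte-like cells derived from a human induced pluripotent stem cell line and from its THRB-knockout derivative. Per the labels' protocols, cells were differentiated to day 25, and T3 (triiodothyronine, the active thyroid hormone) was given at 100 nM for 24 h. Per the same protocols, the medium of the last days held HGF, oncostatin M, vitamin K and dexamethasone. Column-purified RNA was made into stranded libraries of polyadenylated RNA. The labels give 4 groups of 3 libraries: WT control, WT T3, THRB knockout control and THRB knockout T3. They do not say whether control cultures received vehicle or a change of medium, what the THRB lesion is, how many clones were used, or whether replicates are separate cultures. If replicates are not separate cultures, the p-values measure only the spread between these samples.

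The deposited table holds raw counts per gene, which the authors made with featureCounts from Subread on GRCh38, per the submitters' processing notes. These notes also name edgeR and limma, whose roles, like the versions, the annotation release, the strand setting and the handling of reads with several matches, are not given in the sources used here. The values are whole numbers with a different total in each library. The table had 33551 entries, of which 13 were not human genes and held 0 counts, which left 33538 genes. Genes are identified by symbol. Positions came from GENCODE 29 on GRCh38 through the symbol, and 15608 of the 15755 genes tested had a match. Because the strand setting is not given, values of overlapping and antisense genes are uncertain, as are those of near-identical copies such as SAA1 and SAA2 or members of the UGT2B and CYP3A families. Chromosome Y genes, XIST and a few other genes that the rule for named genes took are not reported here.

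Total counts ran from 16301370 to 26043299 per library. A count of 0 was given a floor of 3 counts over the group of 3 libraries, and ratios that rest on 1 to 3 counts have an exact 95% counting interval. Such intervals and floors cover counting error only, since the reads carry no molecular identifiers.

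Genes with low counts were removed with edgeR's filterByExpr (minimum count 10, by group), which left 15755 genes. Counts were scaled with TMM factors and are given as CPM, counts scaled to a common library total. All 12 libraries entered a single model with a mean per group, fitted with edgeR 4.0.16 (quasi-likelihood, robust) in R 4.3.3. Of the 5 contrasts, 4 compare a pair of groups: T3 against control in each genotype, and knockout against WT in each treatment. The last is the interaction, the T3 effect in the knockout line minus that in WT. Each gene was tested with edgeR's quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over all genes tested, and called at an adjusted p under 0.05. All adjusted p-values of single genes come from this test unless another tool is named. Errors of log2 fold changes are standard errors, and errors of CPM are standard deviations over 3 libraries.

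For gene lists, 32 lists with 607 different genes were written before the data were examined, as were the contrasts, the tests and the rule for naming genes. They cover thyroid hormone, lipid, glucose, amino acid, iron and drug metabolism, secreted liver proteins, markers of hepatocytes and of other cell types, and stress and signalling responses. Lists were tested with limma's camera (limma 3.58.1) with a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 32 lists of a contrast. Beside it stand the members called over all genes, the members called when adjusted over the list alone, and camera with an estimated correlation. The text names THRB, THRA, a few genes fixed in advance, the 6 called genes with the largest rise and the 6 with the largest fall per contrast (mean CPM of at least 5, with no overlap between replicates), and up to 4 called members per list with the smallest p. The genes in the account of T3 effects in the knockout line that fall outside this rule, the genes near 0 in that line and the immediate-early list were chosen after the values were seen.

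Overlaps of called genes were set against n1 × n2 / N with a one-sided Fisher's exact test. Contrasts with shared control libraries were also simulated with unchanged groups 20 times. THRB and THRA levels were compared between genotypes with a two-sided exact permutation test.

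The model was tested on simulated data with the real means, spread and library sizes and 200 changed genes. For the T3 effect in WT it called 17 of 67 genes changed 1.5-fold, 40 of 67 changed 2-fold and 56 of 66 changed 4-fold. For the interaction it called 1 of 67, 25 of 67 and 45 of 66. It made 0 to 7 false calls per contrast. The list with a simulated shift was called, and 0 unshifted lists were. Genes were simulated independently of each other, so this cannot show how camera behaves where the genes of a list vary together.

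Alternatives were DESeq2 1.42.0, limma-voom, other scaling factors, other filters on low counts, fits on 6 libraries, the replicate number as a block, an estimated correlation, other thresholds for overlaps, and leaving out each library in turn. Leaving out both knockout libraries numbered 3 was added after seeing the data. All 12 libraries were used. Figures were drawn with matplotlib 3.10.9.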

Results

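The transcriptomes of hepatocyte-like cells derived from human induced pluripotent stem cells were measured by RNA sequencing, with and without T3, in a WT line and in the line labelled THRB knockout. THRB encodes thyroid hormone receptor beta, the main T3 receptor of liver, and THRA encodes the alpha receptor. Each of the 4 groups had 3 libraries. Total counts were 22405029, 26043299 and 20708574 in the WT controls, 24656377, 20917057 and 24683812 in WT with T3, 20524868, 24197366 and 19365816 in the knockout controls, and 16753078, 16301370 and 22779060 in the knockout line with T3. Between 19199 and 20551 genes had at least 1 count. AFP, the fetal serum protein, took 5.22% to 8.78% of all counts in a library. Mitochondrial transcripts took 7.82% to 9.12%. The knockout control 3 and knockout T3 3 libraries stood apart from their groups: against the other replicates their chi-square per degree of freedom was 39.4 and 40.2 in the controls and 35.9 and 16.6 with T3, while replicates 1 and 2 gave 8.69 and 8.37. The WT controls also spread widely: library 1 gave 19.4 and 37.2 against libraries 2 and 3, which gave 14.2 against each other.

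THRB transcript was present at similar levels in both lines. THRB (chromosome 3, 24117153 to 24495756, GRCh38) measured 60.9, 51.3 and 52.8 CPM in the WT controls, 60.7, 47.1 and 53.3 in WT with T3, 52.7, 56.8 and 40.4 in the knockout controls, and 55.2, 52.1 and 43.2 in the knockout line with T3. Its mean was 54.3 ± 5.46 CPM in WT and 50.1 ± 6.68 in the knockout line (n = 6 and 6, two-sided exact permutation p = 0.247). THRA (chromosome 17, 40058290 to 40093867) measured 17.3 ± 1.41 and 16.6 ± 3.11 CPM (exact permutation p = 0.639). Within the knockout line THRA averaged 14.4 ± 2.89 CPM without T3 and 18.8 ± 1.09 with T3, and it was not among the genes called for T3 there. A count over the whole gene cannot show whether an edit of a few bases is present, so THRB counts neither check nor contradict the genotype labels.

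**Figure D1:**
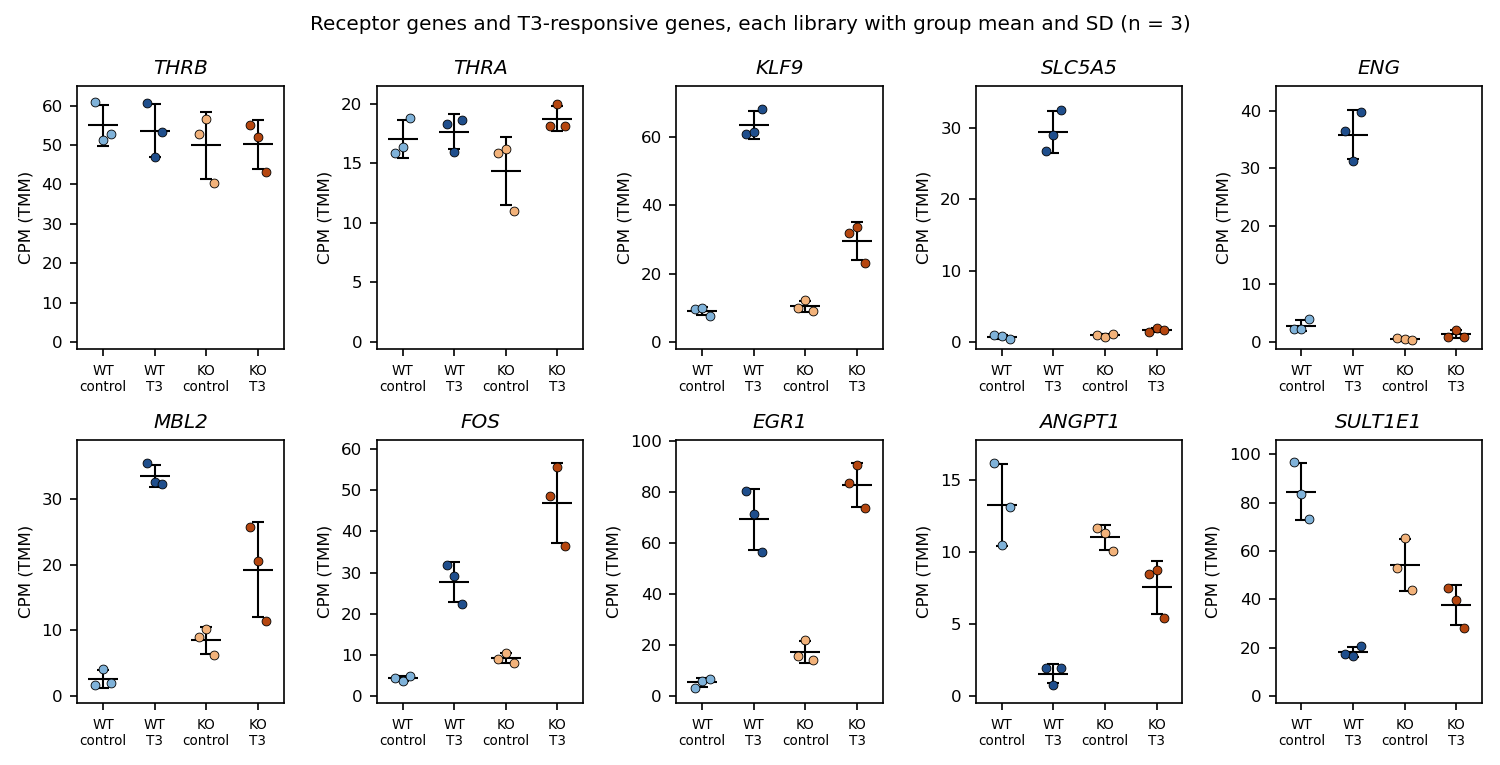
TMM-scaled CPM of 10 genes in each of the 12 libraries (points), with the mean and standard deviation of 3 libraries for each of the 4 groups. THRB lies at similar levels in all groups, and the group means of THRA run from 14.4 to 18.8 CPM. KLF9 averages 63.6 CPM in WT with T3 and 29.5 CPM in the knockout line with T3.

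In WT cells T3 changed many genes, which addresses what the hormone does where its beta receptor gene is intact. SLC5A5, the sodium-iodide symporter, rose from 0.754 ± 0.269 to 29.5 ± 2.92 CPM (n = 3 each, log2 fold change 5.27 ± 0.23, adjusted p = 3.5e-09). KLF9, a transcription factor induced directly by T3 in many tissues, rose from 9.07 ± 1.29 to 63.6 ± 4.09 CPM (2.81 ± 0.16, adjusted p = 3.2e-08). ENG, a TGF-beta co-receptor, rose from 2.85 ± 0.904 to 35.9 ± 4.28 CPM, and MBL2, a complement-activating lectin made by hepatocytes, from 2.61 ± 1.32 to 33.5 ± 1.71. ANGPT1, a ligand of the TEK receptor, fell from 13.3 ± 2.83 to 1.54 ± 0.655 CPM, and SULT1E1, which sulfates estrogens, from 84.6 ± 11.8 to 18.3 ± 2.16.

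Other genes with large increases were the transcription factor gene EGR1 (3.70 ± 0.24), the metalloproteinase gene MMP11 (3.70 ± 0.19) and the collagen gene COL2A1 (3.55 ± 0.16). Other large decreases were those of MS4A10 (−3.46 ± 0.56), TFEC (−2.33 ± 0.46), CALB1 (−2.29 ± 0.29) and FMO1 (−2.28 ± 0.20). AFP changed by −0.52 ± 0.13 (adjusted p = 0.0103), a call that ended without WT control 1 (−0.39, adjusted p = 0.0527). ALB (−0.55 ± 0.21, adjusted p = 0.0915), HR, a T3 target in other tissues (1.52 ± 0.53, adjusted p = 0.0664), and DIO1, a T3 target of liver (−0.06 ± 0.25, adjusted p = 0.911), did not pass. THRSP, a T3 target of liver, lay at 0.115 ± 0.0710 and 0.0970 ± 0.0998 CPM and was not tested.

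edgeR called 2707 of 15755 genes, 1423 higher and 1284 lower with T3, of which 474 and 288 changed at least 2-fold. The total was 1423 without WT control 1, 1601 without WT control 2, and 1598, 1569 and 1599 without WT T3 1, 2 and 3, and no called gene changed sign in these fits.

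In WT cells T3 raised genes of lipid synthesis and changed genes of fatty acid oxidation in both directions, more of them downward. Of 21 tested genes of fatty acid and triglyceride synthesis, 8 rose and 0 fell, among them the elongase gene ELOVL6 (1.10 ± 0.11) and MLXIPL, the carbohydrate-response transcription factor (2.28 ± 0.35). Adjusted over the list alone the counts were also 8 and 0 (median log2 fold change 0.28, camera adjusted p = 0.00317; adjusted p = 0.938 with an estimated correlation). Of 24 genes of mitochondrial fatty acid oxidation and ketogenesis, 8 fell and 3 rose, and 9 and 3 did adjusted over the list alone (median −0.27, camera adjusted p = 0.0142; adjusted p = 0.938 with an estimated correlation). ACAA2, a mitochondrial thiolase, fell (−0.77 ± 0.11), as did the acyl-CoA dehydrogenase gene ACADSB (−1.06 ± 0.19), while ETFB, an electron carrier for fatty acid oxidation, rose (2.35 ± 0.22). CPT1A, the rate-limiting enzyme of fatty acid entry into mitochondria, also rose, from 0.880 ± 0.327 to 3.97 ± 1.69 CPM (2.15 ± 0.60, adjusted p = 0.0272), a call that ended without WT control 1 (adjusted p = 0.104), WT control 2 (0.0547) or WT T3 1 (0.105) and without a filter on low counts (0.103). Cholesterol synthesis had 7 higher and 0 lower of 24 (also 7 and 0 adjusted over the list alone), with a camera adjusted p of 0.0731.

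Genes listed in advance as T3 targets rose as a group, 7 of 14 with 0 lower (8 and 0 adjusted over the list alone; median 0.93, camera adjusted p = 4.42e-05; adjusted p = 0.182 with an estimated correlation). They include PCK1, the key enzyme of gluconeogenesis (2.99 ± 0.47), and SHBG, the sex hormone carrier (1.30 ± 0.27). Of 16 glucocorticoid target genes 6 rose and 0 fell (6 and 1 adjusted over the list alone; median 0.34, camera adjusted p = 0.000309; adjusted p = 0.0575 with an estimated correlation), among them KLF9 itself, PER2 (1.31 ± 0.23) and DUSP1 (1.16 ± 0.14).

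A further 3 lists passed camera in the upward direction, though most of their members were not called. Cell cycle genes had 6 of 27 higher and 0 lower, the same counts adjusted over the list alone, with MCM6, a replication helicase subunit, at 0.95 ± 0.14 (median 0.23, camera adjusted p = 0.0487; adjusted p = 0.938 with an estimated correlation). Among p53 targets 7 of 20 were higher and 0 lower, or 9 and 0 adjusted over the list alone, such as TP53I3 at 1.17 ± 0.15 (median 0.18, camera adjusted p = 0.0426; adjusted p = 0.846 with an estimated correlation). The interferon response had 5 of 19 higher and 1 lower, or 7 and 1 adjusted over the list alone, such as IFIT3 at 1.39 ± 0.15 and MX1 at 1.41 ± 0.16 (median 0.45, camera adjusted p = 0.0426; adjusted p = 0.658 with an estimated correlation). The cell cycle median was 0.04 without WT T3 1, 0.13 without WT control 2 and 0.38 without WT control 3, and the interferon median was 0.26 without WT T3 1. At least 1 of these 3 lists no longer passed without WT control 1 (adjusted p up to 0.0620), WT control 2 (up to 0.119), WT T3 1 (up to 0.144), WT T3 3 (0.0626), knockout control 1 (0.0531) or knockout T3 1 (0.0570), and the cell cycle and interferon lists gave 0.0637 without both knockout libraries 3. With a stricter filter on low counts the cell cycle (0.0714) and p53 (0.0655) calls ended.

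Genes of bile and drug handling moved in both directions. SLC51B, a bile acid exporter subunit, rose (2.29 ± 0.15), as did ABCB4, the phospholipid exporter of bile (3.19 ± 0.49), while ABCB11, the bile salt export pump, fell (−1.25 ± 0.26). Of 20 bile acid genes 4 rose and 2 fell, as adjusted over the list alone (median −0.11, camera direction up, adjusted p = 0.715). Drug metabolism had 7 higher and 4 lower of 25, or 7 and 7 adjusted over the list alone (median −0.30, camera direction up, adjusted p = 0.997). Of 20 genes of the unfolded protein response 8 fell and 4 rose (9 and 6 adjusted over the list alone; camera adjusted p = 0.461). The endoplasmic reticulum chaperone genes HSPA5 (−0.72 ± 0.10) and HSP90B1 (−0.79 ± 0.11) were among those that fell, and SESN2 (0.74 ± 0.11) among those that rose. GLUL, glutamine synthetase, rose (1.68 ± 0.16), as did STEAP3, an iron reductase (1.58 ± 0.13).

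In the line labelled THRB knockout, the same treatment gave far fewer calls, which addresses how much T3 action remains. FOS, the immediate-early transcription factor gene, rose from 9.18 ± 1.17 to 46.9 ± 9.67 CPM (n = 3 each, log2 fold change 2.35 ± 0.18, adjusted p = 1.6e-05). EGR1, of the same early-response class, rose from 17.4 ± 4.23 to 82.7 ± 8.52 CPM (2.25 ± 0.22, adjusted p = 0.000473). KLF9 rose from 10.5 ± 1.60 to 29.5 ± 5.63 CPM (1.49 ± 0.16, adjusted p = 0.000473), and SLC25A25, a mitochondrial carrier gene, rose too (1.23 ± 0.13). CLK1 (−0.82 ± 0.10) and RSRP1 (−0.78 ± 0.11), which act in RNA splicing, fell. SLC5A5 measured 0.942 ± 0.153 CPM without and 1.70 ± 0.253 with T3.

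edgeR called 24 genes, 21 higher and 3 lower, of which 11 and 1 changed at least 2-fold, while 1222 genes had an unadjusted p under 0.05 and chance gives 788. The total was 12 without knockout control 1, 15 without knockout control 2, 58 without knockout control 3, 10 without knockout T3 2 and 15 without WT T3 3, and without knockout T3 2 RSRP1 had an adjusted p of 0.0613. With the 6 knockout libraries alone in the fit, CLK1 (adjusted p = 0.0643) and RSRP1 (0.170) no longer passed. DESeq2 called 82 higher and 27 lower, and limma-voom called 17 and 3. FOS, EGR1, KLF9 and SLC25A25 passed in every alternative fit.

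Of the glucocorticoid target genes KLF9, also a listed T3 target, and DUSP1, also an immediate-early gene, were called higher in the knockout line. The glucocorticoid list also rose as a group there, 2 of 16 with 0 lower, or 4 and 1 adjusted over the list alone. This was the list whose call also held with an estimated correlation (median 0.30, or 0.18 without knockout control 1 and 0.14 without knockout T3 3; camera adjusted p = 0.000211; adjusted p = 0.0415 with an estimated correlation). The T3 target list had 1 of 14 higher, KLF9, also 1 adjusted over the list alone (median 0.09, camera adjusted p = 0.0296; adjusted p = 0.629 with an estimated correlation). Its median was 0.32, 0.27 and −0.01 without knockout controls 1, 2 and 3, 0.18 and 0.20 without knockout T3 1 and 2, and 0.03 without both libraries 3. A further 8 lists passed camera without a called member. TGF-beta and matrix genes (adjusted p = 0.838 with an estimated correlation), p53 targets (0.838), fibroblast markers (0.838) and endothelial markers (0.629) leaned higher. The fibroblast median of 0.25 was 0.10 without knockout control 1 and 0.56 without knockout control 3. The endothelial median of 0.34 was 0.89 without knockout control 1, 0.15 without knockout T3 2 and −0.03 without a filter on low counts. Fatty acid oxidation (adjusted p = 0.838 with an estimated correlation), the urea cycle (0.839), coagulation (0.882) and mature hepatocyte markers (0.882) leaned lower. The coagulation median of −0.09 turned to 0.04 without knockout control 1 and was −0.29 without knockout control 3. That of the urea cycle, −0.14, was −0.03 and −0.36 in these fits. Adjusted over the list alone, 2 endothelial markers were higher and 0 members of the other 7 lists passed. At least 1 of these 9 calls ended without knockout control 1 (adjusted p up to 0.734), control 2 (up to 0.424), control 3 (up to 0.487), T3 1 (up to 0.272), T3 2 (up to 0.204) or T3 3 (up to 0.107) of the knockout line, and the T3 target call ended without both libraries 3 (0.217). Without a filter on low counts the T3 target (0.0517) and endothelial (0.199) calls ended, and with a stricter filter those of coagulation (0.203) and fibroblast markers (0.0560).

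The T3 effects of WT cells mostly had the same direction in the knockout line and a smaller size. Of the 2707 genes called in WT, 2458 (90.8%) had the same sign in the knockout line, and 98.9% had a smaller effect there. An effect of opposite sign counted as smaller whatever its size, so unrelated effects would also give a high share. These genes were chosen for their effect in WT, which favours a smaller effect in the other line. Over all 15755 tested genes 71.9% had the same sign and 80.1% a smaller effect by the same count. The median effect of the genes raised in WT was 0.77 in WT and 0.24 in the knockout line, and that of the genes lowered was −0.59 and −0.20. The slope of knockout on WT effects over the called genes was 0.282. Of the 21 genes raised in the knockout line 20 were also raised in WT, where 1.90 would be shared by independent lists (one-sided Fisher's exact p = 2.2e-20), and all 3 genes lowered there were lowered in WT, where 0.244 would be (exact p = 0.00054). The remaining raised gene was DLEC1 (1.90 ± 0.35 in the knockout line and 0.77 ± 0.32 in WT, interaction adjusted p = 0.421). Across all tested genes, which are not independent replicates, the effects had a Pearson correlation of 0.412 and a Spearman correlation of 0.523. Without both knockout libraries 3 the same-sign share was 69.0%, over the genes called in WT in that fit rather than these 2707.

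**Figure D2:**
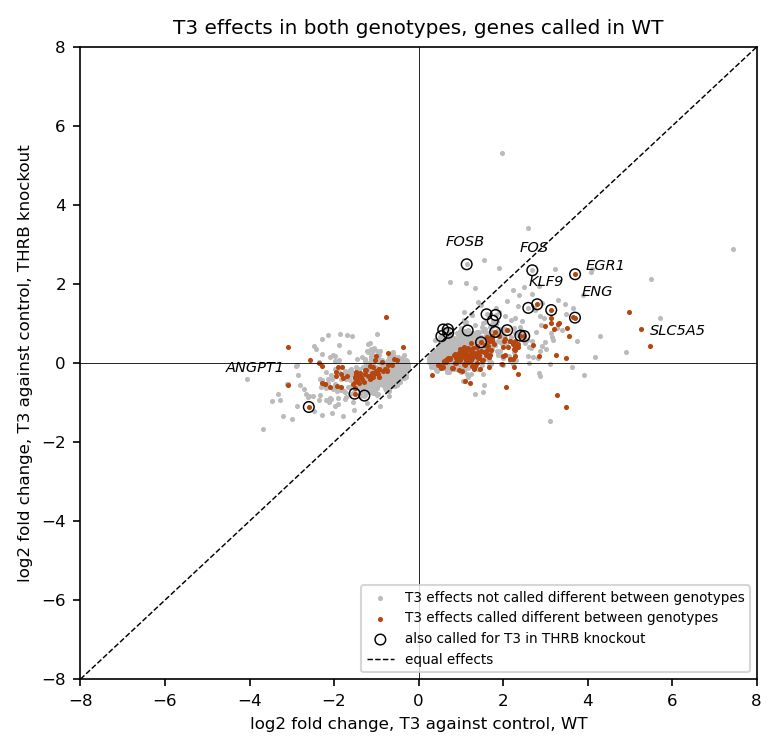
Log2 fold change with T3 in WT (horizontal axis) and in the line labelled THRB knockout (vertical axis) for the 2707 genes called in WT, with the 222 genes called in the interaction in red, genes also called in the knockout line circled, and a dashed line where effects would be equal. Most points lie between that line and 0, with a slope of 0.282.

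Tested directly, T3 effects differed between the genotypes for 222 genes, and nearly all were weaker in the knockout line. SLC5A5 had a T3 effect 4.41 ± 0.35 log2 units smaller in the knockout line (difference −4.41, adjusted p = 1.6e-05). The tight-junction gene CLDN2 had a difference of −3.36 ± 0.40, COL2A1 of −2.87 ± 0.21, MMP11 of −2.55 ± 0.25 and KLF9 of −1.32 ± 0.22 (adjusted p = 0.00521). Among genes that T3 lowered in WT, the difference was 2.54 ± 0.38 for ANGPT1, 2.20 ± 0.40 for CALB1, 1.78 ± 0.27 for FMO1 and 1.68 ± 0.25 for SULT1E1. The metabolic genes ELOVL6 (−0.98 ± 0.16), ETFB (−1.86 ± 0.31), SLC51B (−2.11 ± 0.22) and GLUL (−1.78 ± 0.22) differed as well.

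Of the 222 genes, 151 were raised by T3 in WT, and all of these had an effect of smaller absolute size in the knockout line. The other 71 were lowered in WT, and 69 had an effect of smaller absolute size in the knockout line. An opposite sign in the knockout line was seen for 26 and 11 of them, and 9 and 2 were also called there. MBL2, whose T3 effect differed by −2.48 ± 0.45 (adjusted p = 0.0179), lost its call without WT T3 1 (adjusted p = 0.0528) and without a filter on low counts (0.0946). MBL2 also measured 8.47 ± 2.04 CPM in the knockout controls against 2.61 ± 1.32 in the WT controls. Its higher untreated level therefore enters that difference. The edgeR total was 136 without knockout control 1, 362 without knockout control 3, 142 and 120 without knockout T3 1 and 2, 147 and 127 without WT controls 1 and 2, and 99, 127 and 113 without WT T3 1, 2 and 3.

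By list, T3 target genes had a smaller T3 effect in the knockout line (median difference −1.01, or −0.66 without WT T3 1; 1 of 14 called, 3 adjusted over the list alone; camera adjusted p = 7.61e-05; adjusted p = 0.379 with an estimated correlation). So did fatty acid and triglyceride synthesis (median −0.30, or −0.52 without knockout control 3; 2 of 21 called, also 2 adjusted over the list alone; camera adjusted p = 2.65e-05; adjusted p = 0.561 with an estimated correlation). Cholesterol synthesis had a median difference of −0.28, or −0.16 without WT T3 1 and −0.18 without knockout control 1, with 0 of 24 called (camera adjusted p = 0.00726; adjusted p = 0.818 with an estimated correlation). Glycolysis had −0.27 with 1 of 17 called (camera adjusted p = 0.0320; adjusted p = 0.818 with an estimated correlation). Endothelial and blood cell markers had 0.37, or 0.57 without WT control 2 and 0.82 without knockout control 1, with 0 of 10 called (camera adjusted p = 0.0343; adjusted p = 0.561 with an estimated correlation). Adjusted over the list alone, 0, 1 and 2 members of these last 3 lists passed. At least 1 of these 3 calls ended without WT control 1 (adjusted p = 0.129), WT control 3 (up to 0.0905), WT T3 1 (0.0791), 2 (0.0758) or 3 (0.0747), knockout control 1 (0.0645), knockout control 3 (0.100), knockout T3 2 (up to 0.159) or knockout T3 3 (0.121), and the endothelial call without a filter on low counts (0.119). Mean untreated levels of these lists differed too. T3 targets averaged 2.50 ± 0.07 in the WT and 2.84 ± 0.32 in the knockout controls, in log2(CPM + 1). With T3 they averaged 3.36 and 3.01. Cholesterol synthesis averaged 7.07 ± 0.11 and 7.32 ± 0.26, and 7.30 and 7.30 with T3. Fatty acid synthesis and glycolysis also started higher in the knockout controls, and endothelial markers lower. The differences by list are therefore not ones of T3 response alone.

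Without T3, the line labelled THRB knockout differed from WT in single genes by large factors. LY6E, a membrane protein gene (chromosome 8, 143017982 to 143023832), had 5713 counts in the 3 WT controls and 0 in the 3 knockout controls, at least 1700-fold lower against a floor of 3 counts over the group. TSPYL5 (chromosome 8, 97273474 to 97277964) had 2521 and 0 counts, at least 750-fold lower. ZNF680, a zinc finger gene, had 1218 counts in WT and 1 in the knockout line, a ratio of 1087 (95% counting interval 195 to 42953). CNTN4, a neuronal adhesion gene, was higher in the knockout line, at 75.5 ± 4.09 against 1.29 ± 0.250 CPM (n = 3 each, log2 fold change 5.85 ± 0.17), as was ZNF528 at 34.5 ± 2.85 against 0.715 ± 0.152 CPM. TF, the iron carrier transferrin, measured 13246 ± 1479 CPM in WT and 407 ± 242 in the knockout line (−5.02 ± 0.45, adjusted p = 2.0e-05).

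Many genes of secreted liver proteins were higher in the knockout line, though not all: TF was lower, and APOA1 (−0.28 ± 0.18, adjusted p = 0.425) and APOB (0.17 ± 0.15, adjusted p = 0.577) did not pass. ALB, serum albumin, measured 599 ± 75.4 CPM in the WT and 1643 ± 556 in the knockout controls (1.46 ± 0.21, adjusted p = 0.00111). Of 26 complement and acute phase genes 18 were higher and 0 lower, or 21 and 1 adjusted over the list alone, among them FGL1 (2.45 ± 0.21), C8A (2.25 ± 0.23) and the iron hormone HAMP (2.66 ± 0.28). The list had a median of 1.27 (camera adjusted p = 6.49e-29; adjusted p = 0.160 with an estimated correlation), or 1.54 without both knockout libraries 3. Of 22 coagulation genes 13 were higher and 0 lower, or 15 and 0 adjusted over the list alone, such as KNG1 (1.61 ± 0.18) and F5 (1.22 ± 0.17). Their median was 0.73 (camera adjusted p = 3.51e-15; adjusted p = 0.169 with an estimated correlation), or 0.80 without those libraries. AFP did not pass (0.14 ± 0.13, adjusted p = 0.588).

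Fibroblast and endothelial markers were lower, while cholangiocyte (1 of 18 higher, 1 lower; camera adjusted p = 0.916), gut (0 of 10 higher, 2 lower; 0.625) and pluripotency markers (1 of 7 higher, 0 lower; 0.153) did not pass. Of 18 fibroblast and stellate cell markers 7 were lower and 0 higher, or 11 and 3 adjusted over the list alone, among them the collagen gene COL1A2, at 330 ± 119 CPM in WT and 74.7 ± 16.3 in the knockout controls (−2.14 ± 0.24). The median was −1.24 (camera adjusted p = 1.29e-06; adjusted p = 0.294 with an estimated correlation), or −1.47 without both knockout libraries 3. Of 10 endothelial and blood cell markers 5 were lower and 0 higher, or 6 and 0 adjusted over the list alone, such as CDH5 (−3.36 ± 0.46) and the VEGF receptor gene KDR (−4.07 ± 0.62). Their median was −1.55 (camera adjusted p = 0.000260; adjusted p = 0.169 with an estimated correlation), or −1.21 without those libraries. Cell cycle genes were higher, 8 of 27 with 0 lower, or 13 and 0 adjusted over the list alone, such as MKI67 (1.31 ± 0.21) and TOP2A (1.10 ± 0.17), with a camera adjusted p of 5.77e-08 (adjusted p = 0.169 with an estimated correlation) and a median of 0.49, or 0.52 without those libraries.

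A further 9 lists of liver function and metabolism passed camera in the upward direction. They were drug metabolism (8 of 25 higher, 1 lower; adjusted p = 0.338 with an estimated correlation), fatty acid synthesis (4 of 21 higher; 0.454), urea cycle and amino acid catabolism (3 of 16 higher; 0.454), glycolysis (2 of 17 higher; 0.443) and bile acids (5 of 20 higher; 0.455). The others were mature hepatocyte markers (6 of 23 higher, 1 lower; adjusted p = 0.561 with an estimated correlation), lipoproteins (4 of 22 higher, 1 lower; 0.455), fetal liver markers (4 of 13 higher, 1 lower; 0.160) and cholesterol synthesis (4 of 24 higher; 0.561). Adjusted over the list alone, these 9 lists had 8, 6, 6, 6, 8, 9, 7, 5 and 4 higher members in this order. The cholesterol call ended without WT control 3 (adjusted p = 0.0581) or knockout control 1 (0.0537).

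edgeR called 1281 genes, 597 higher and 684 lower in the knockout line, of which 270 and 344 differed at least 2-fold. The share higher was 46.6%, or 35.0% when scaled by library size alone, and the total was 690 without knockout control 1 and 754 without WT control 2. The labels name a single derived line, so differences made by the THRB lesion and differences between lines are not separable here.

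**Figure D3:**
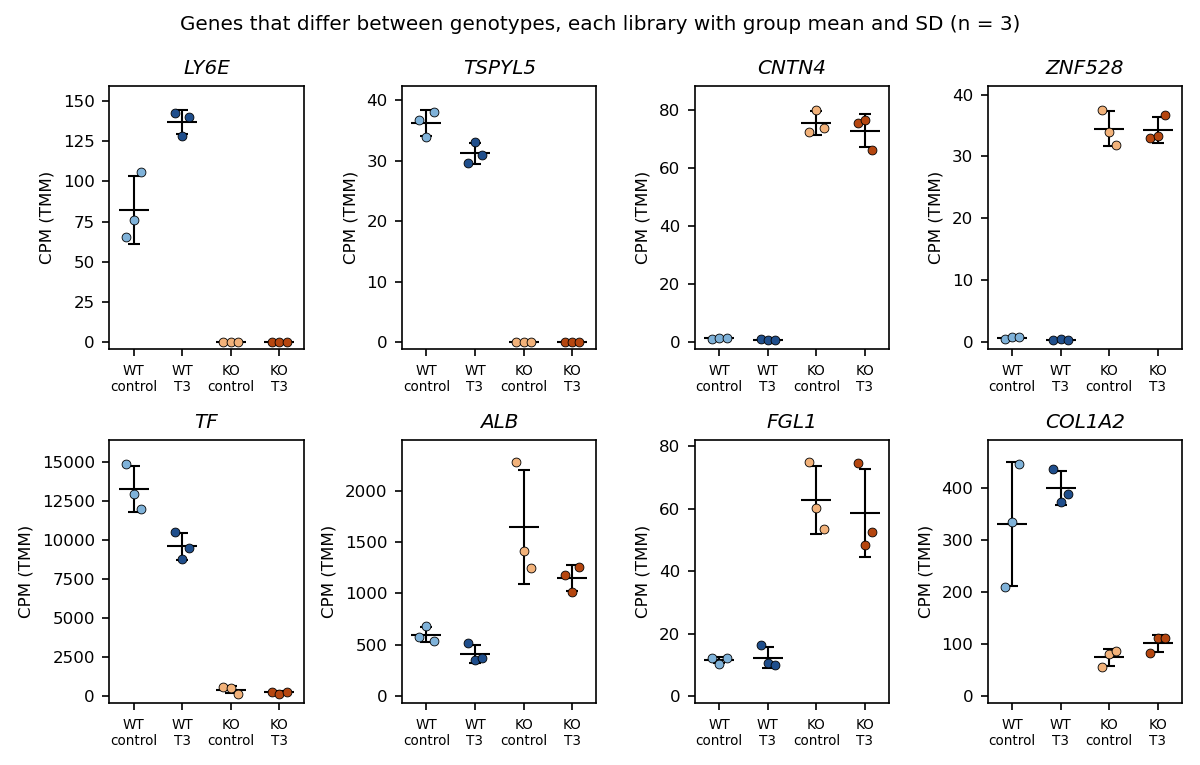
TMM-scaled CPM of 8 genes in each of the 12 libraries (points), with the mean and standard deviation of 3 libraries for each of the 4 groups. Group means of LY6E and TSPYL5 are at most 0.0204 CPM in the knockout line, and those of CNTN4 and ZNF528 at most 1.29 CPM in WT.

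With T3 the differences between the lines included the genes that respond to T3. SLC5A5 was lower in the knockout line (−4.11 ± 0.21, adjusted p = 6.9e-09), as were ENG at 1.33 ± 0.713 against 35.9 ± 4.28 CPM (−4.78 ± 0.31), KLF9 (−1.11 ± 0.15), PCK1 (−2.53 ± 0.46), SLC51B (−2.29 ± 0.16) and GLUL (−1.99 ± 0.16). ABCB11 (2.03 ± 0.25) was higher. ENG already measured less in the knockout line without T3, at 0.494 ± 0.242 against 2.85 ± 0.904 CPM, so its difference with T3 is not one of T3 response alone. Some line differences seen without T3 were called again: of the 597 higher and 684 lower genes, 328 and 293 were called in the same direction with T3, and 21 and 6 were called the opposite way. LY6E had 9892 counts in WT and 1 in the knockout line, a ratio of 7605 (95% counting interval 1365 to 300399), TSPYL5 was at least 574-fold lower (2240 and 0 counts), and TF measured 9573 ± 850 and 225 ± 63.4 CPM. ZNF528 (6.49 ± 0.19) and CNTN4 (6.39 ± 0.18) were again higher, as was ALB (1.49 ± 0.21).

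Complement and acute phase genes were again higher in the knockout line, 14 of 26 with 1 lower, or 18 and 2 adjusted over the list alone, such as FGL1 (2.25 ± 0.21), with a median of 0.79 (camera adjusted p = 1.95e-18; adjusted p = 0.247 with an estimated correlation), or 0.87 without both knockout libraries 3. Coagulation had 9 of 22 higher and 0 lower, or 12 and 1 adjusted over the list alone, such as HRG at 2.61 ± 0.29 (camera adjusted p = 5.70e-07; adjusted p = 0.654 with an estimated correlation). Cell cycle had 7 of 27 higher and 1 lower, MCM6 (−0.96 ± 0.14), or 13 and 1 adjusted over the list alone (camera adjusted p = 0.00119; adjusted p = 0.654 with an estimated correlation). Fibroblast markers had 7 of 18 lower and 0 higher, also 7 and 0 adjusted over the list alone, such as COL1A2 at −1.98 ± 0.24 (camera adjusted p = 0.00119; adjusted p = 0.654 with an estimated correlation), and a median of −0.86, or −0.77 without those libraries and −0.51 without WT T3 1.

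Of the urea cycle list 6 of 16 were higher, among them OTC (2.22 ± 0.39), with adjusted p = 0.654 with an estimated correlation, and of fatty acid oxidation 5 of 24 were higher and 1 lower (adjusted p = 0.699 with an estimated correlation). Mitochondrially encoded mRNAs had 4 of 13 higher (adjusted p = 0.725 with an estimated correlation), fetal liver markers 3 of 13 (0.247), drug metabolism 7 of 25 with 2 lower (0.654) and mature hepatocyte markers 8 of 23 with 2 lower (0.776). Adjusted over the list alone, these 6 lists had 7, 9, 4, 6, 8 and 12 higher members in this order. Of these, the mitochondrial, drug metabolism and mature hepatocyte calls ended without knockout T3 1 (adjusted p up to 0.100), the last pair without WT T3 2 (up to 0.148), and the mature hepatocyte call also without WT T3 3 (0.0864) or knockout control 3 (0.0863). The endothelial (adjusted p = 0.122), fatty acid synthesis (0.680), glycolysis (0.498), bile acid (0.188), lipoprotein (0.236; median −0.12, camera direction up) and cholesterol lists (0.956; median 0.01, camera direction down), which passed without T3, did not pass with T3.

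edgeR called 1811 genes between the lines with T3, 891 higher and 920 lower in the knockout line, of which 339 and 414 differed at least 2-fold. The total was 1142 and 1152 without knockout T3 1 and 2, and 1172, 1180 and 1098 without WT T3 1, 2 and 3.

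**Figure D4:**
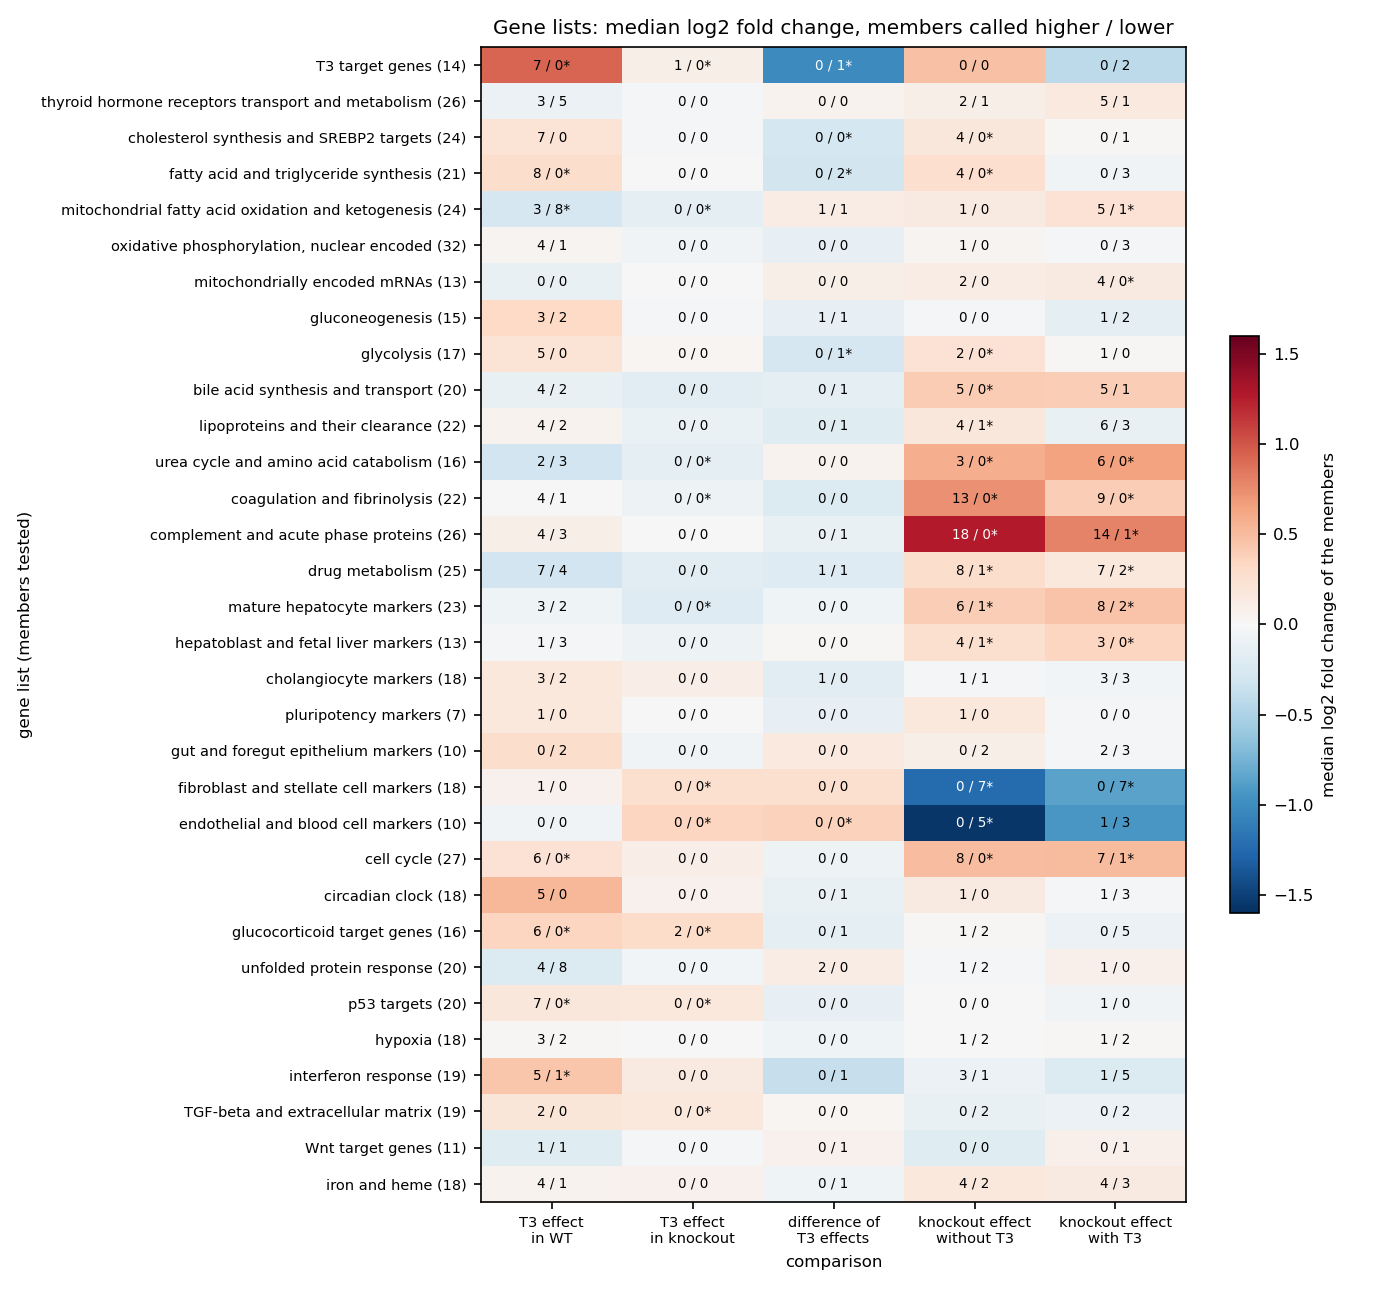
Median log2 fold change of the tested members of each of the 32 gene lists (rows) in the 5 contrasts (columns), with the number of members called higher and lower in each cell and an asterisk where camera's adjusted p with the preset correlation was under 0.05. Complement and acute phase genes have the highest median, 1.27, in the knockout line without T3, and T3 target genes have a median of 0.93 with T3 in WT.

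Genes that T3 raised in WT were set against genes already higher in the untreated knockout line, which addresses whether the line resembles T3-treated cells before any T3 is given. Between these contrasts 127 genes were higher in both and 158 lower in both, where independent lists would share 53.9 and 55.7, while 30 and 51 went opposite ways. Both contrasts use the 3 WT control libraries. With unchanged simulated groups against those controls the largest counts were 0 and 0. Such groups hold no changed genes, so these counts cannot show the overlap that shared controls add where many genes are called. The Pearson correlation across genes was 0.170 against 0.498 simulated, and the covariance was 0.0748 against 0.0406 simulated, a difference of 0.0342. When the controls were divided so that none was shared, the covariance ran from −0.0358 to 0.0679, so its sign depended on which control was used for which contrast.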

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

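The tests on the knockout libraries numbered 3, on segments and whole autosomes, and on the share of hepatocyte-like cells were chosen after the result was seen, while the splits of the libraries and the removal of culture axes were fixed earlier.

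A difference of T3 effects between the genotypes was the reason for a closer look at 71 genes with a larger value in the knockout line and 151 with a smaller value, tested as edgeR's interaction. Among named genes that T3 lowered in WT, the difference in log2 was 2.54 for ANGPT1, 2.20 for CALB1, 1.80 for SHISA6, 1.78 for FMO1, 1.68 for PCYT1B, 1.68 for SULT1E1, 1.08 for CREB3L3, 0.66 for HSPA5, 0.65 for HSP90B1 and 0.58 for CFTR. Among those that T3 raised in WT it was −4.41 for SLC5A5, −3.36 for CLDN2, −3.05 for MPV17L, −2.87 for COL2A1, −2.68 for ADH4, −2.55 for MMP11, −2.48 for MBL2, −2.11 for SLC51B, −1.86 for ETFB, −1.78 for GLUL, −1.46 for PER2, −1.32 for KLF9, −1.25 for MX1, −1.11 for STEAP3, −0.98 for ELOVL6, −0.94 for APOC1, −0.88 for PCK2, −0.65 for ACSL3 and −0.59 for PGAM1. The calls of PCYT1B, HSPA5, HSP90B1, CREB3L3, CFTR, ADH4, MBL2, PER2, PCK2, ACSL3 and PGAM1 ended in at least 1 alternative fit. The median difference by list was −1.01 for T3 targets, −0.28 for cholesterol synthesis, −0.30 for fatty acid and triglyceride synthesis, −0.27 for glycolysis and 0.37 for endothelial and blood cell markers. Mean untreated levels of these lists also differed between the lines, so these values are not differences of T3 response alone. Leaving out WT T3 1 moved the T3 target median to −0.66 and that of cholesterol synthesis to −0.16, knockout control 1 moved cholesterol synthesis to −0.18 and the endothelial markers to 0.82, WT control 2 moved the latter to 0.57, and knockout control 3 moved fatty acid synthesis to −0.52. Of 100 splits that mixed labels within genotypes, 12 gave at least the 222 genes called, the real split among them and 3750 the highest of the rest of the 12, so by this count alone chance is not excluded. These 12 kept the WT labels and therefore still hold the whole T3 effect of WT, a structure that gives many calls by itself. The real split had the fewest calls of these 12, and the next had 285. Each of the remaining 88 splits, which mixed the WT labels, called 0 genes. Mixing these labels puts the T3 effect of WT into the spread within groups, which by itself holds calls down. Those 88 splits therefore cannot show whether the interaction calls arise by chance.

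The first pattern is that T3 effects of WT cells lean the same way in the knockout line, at 90.8% of the genes called in WT. With the first 2 axes of variation within groups (25.4% and 19.4% of that variance) removed, the share was 86.5%, and the correlation went from 0.412 to 0.347. This argues against those 2 axes as the whole cause. The rest of the variation within groups stayed in both effects, so other differences between cultures are not excluded. Without both knockout libraries 3 the share was 69.0%, below the full value by more than its jackknife spread of 10.9. That share was taken over the genes called in WT in that fit, a different set from the one behind 90.8%. How far those libraries, or the change of gene set, shape the size of the lean stays open. The real split of the knockout libraries ranked 1 of 10, with 81.3% the highest of the others, and 10 splits are too few for a share under 0.05. THRA, which was expressed, THRB function left by the lesion, and handling or a medium change shared by the T3 cultures, which the labels leave open, all remain as explanations, and none of them was tested.

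The second pattern is the genes near 0 in the knockout line: 11 autosomal genes had at least 1 CPM in all WT libraries and under 0.15 CPM in all knockout libraries, among them LY6E, TSPYL5, ZNF680, ZNF717, ZNF248, ZNF280B and C17orf51, and 3 genes, CNTN6, LINC01090 and HIST1H3E, were near 0 in WT, with values of zinc finger and histone genes uncertain because of close copies. Loss of a segment around each gene is argued against for the 9 genes with at least 2 tested neighbours, since the 102 genes within 1 Mb had a median log2 fold change of −0.0653 (quartiles −0.33 and 0.19). The 2 genes with 1 tested neighbour, LINC00662 and AC006504.5, adjoin on chromosome 19 and share that neighbour, at −7.66. Genes near 0 were not counted as neighbours of each other. This is too few genes to decide, so loss of that stretch stays open. Loss or gain of a whole autosome is argued against by autosome medians of −0.0832 to 0.0682. Such a change would move the genes of an autosome together and not bring single genes near 0. These medians therefore do not bear on the cause of the near-0 genes. Silencing or a local change in the derived line, and an effect of the THRB lesion, remain open and cannot be separated with a single derived line.

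The third pattern is the higher level of hepatic protein genes in the knockout line without T3. Of 48 called members of the 5 hepatic lists, 3 were lower, or 6.25%, namely TF, LPA and EPCAM, but this share restates the pattern and would also come from a change within the cells or between lines, so whether a higher share of hepatocyte-like cells contributes stays open. Fibroblast markers (median −1.24) and endothelial markers (−1.55) were lower in the same contrast, which a shift between cell types and a change within these cells would both give. The 10 hepatic list members most abundant in the WT controls had a median of 0.37 (upper quartile 0.67), below the lower quartile of 0.84 of the complement list. A higher share of hepatocyte-like cells that raised all their genes alike would therefore not give the whole rise of complement and acute phase genes. The complement list was set against these genes after its median, the highest of the lists, was seen. Hepatocyte-like cells may also differ from each other, so the comparison cannot exclude a role of cell shares. A change within hepatocyte-like cells and differences between the lines stay open, as no test here separates them.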

How the results depend on the processing

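Leaving out both knockout libraries 3 was chosen after seeing the data, and the other alternatives were fixed earlier. No named gene with a call changed sign in any alternative, no called gene did when a library was left out, and the cause of the moves below was not tested unless fewer libraries, fewer or more genes, or a changed threshold is the alternative itself. Limma-voom, median-ratio factors, library size alone and the stricter filter left every count of called genes within 1.5 times, and DESeq2 also called 2685 of 2707, 24 of 24, 222 of 222, 1281 of 1281 and 1810 of 1811 of edgeR's calls.

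With a correlation estimated from the data, the lists called were 0 for T3 in WT, 1 for T3 in the knockout line, 0 for the interaction and 0 and 0 for the knockout effect without and with T3. At adjusted p under 0.1 the overlap of T3 effects was 39 higher and 12 lower, and that of the knockout effect without T3 with the T3 effect in WT was 210 and 278. At 0.01 these were 7 higher, and 40 and 34. DESeq2 called 82 higher and 27 lower for T3 in the knockout line and 142 and 257 for the interaction, with an overlap of T3 effects of 70 and 26. Without a low-count filter the knockout line gave 62 and 18, the interaction 118 higher, the overlap 53 and 16, and the correlation of the knockout effect without T3 with the T3 effect in WT was 0.398. With 6 libraries per fit, T3 in the knockout line gave 5 and 0, and the knockout effect without T3 339 and 389.

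Without both knockout libraries 3, T3 raised 2232 genes in WT, and in the knockout line 37 were higher and 8 lower. The interaction had 177 and 364, the knockout effect 899 higher without T3 and 1424 lower with T3, the overlap of T3 effects 36 and 6 with 69.0% of the same sign, and that with the knockout effect 274 and 244. Lists called were 16 for T3 in the knockout line and 12 for the interaction.

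Leaving out each library in turn gave 722 to 1861 higher and 635 to 1628 lower for T3 in WT, 9 to 39 and 1 to 19 for T3 in the knockout line, 27 to 111 and 71 to 251 for the interaction, 348 to 744 and 341 to 735 for the knockout effect without T3, and 579 to 1186 and 500 to 1203 with T3. The overlap of T3 effects was 9 to 38 and 1 to 15, that with the knockout effect 56 to 201 and 44 to 197, and the lists called 3 to 16 for T3 in the knockout line and 3 to 10 for the interaction. In simulation at the real depth with 3 libraries per group, 17 of 67 genes with a 1.5-fold T3 effect were called in WT.

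Of 18 correlations between libraries of the same number, 3 were over 0.1 (range −0.133 to 0.352). The highest were 0.305 and 0.352, between the WT control and knockout T3 libraries 1 and 3. Libraries of different numbers were not compared, so whether replicate numbers pair the libraries was not tested. With the replicate block the calls were 2746, 27, 237, 1242 and 1849, against 2707, 24, 222, 1281 and 1811 without it, for T3 in WT, T3 in the knockout line, the interaction and the knockout effect without and with T3. Among the calls that changed with the block were the cell cycle and interferon lists for T3 in WT, with an adjusted p of 0.0521 each.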

Other observations

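The tests on immediate-early genes and the overlap of the knockout effects were chosen after the result was seen, and the splits of the libraries were fixed earlier.

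T3 also changed genes of thyroid hormone handling in WT cells. IYD, which recovers iodide (−1.07 ± 0.18), SLC16A10, an aromatic amino acid and thyroid hormone transporter (−1.29 ± 0.22), and SERPINA7, the thyroxine-binding globulin of plasma (−1.13 ± 0.22), fell, and CRYM, a cytosolic T3-binding protein, rose (1.08 ± 0.17). Of the 26 genes of this list 3 rose and 5 fell (camera adjusted p = 0.236). Among clock genes 5 of 18 rose and 0 fell (camera adjusted p = 0.0701), and among amino acid enzymes OTC of the urea cycle fell (−2.06 ± 0.38), as did TDO2 (−1.19 ± 0.22). FBP1, an enzyme of gluconeogenesis, fell (−1.76 ± 0.34) while PCK1 rose (2.99 ± 0.47), and 3 genes of that list rose and 2 fell (camera adjusted p = 0.706).

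Part of the line difference was called in both treatments, which use different libraries. Of 597 genes higher in the knockout line without T3, 328 were also called higher with T3, where independent lists would share 33.8, and of 684 lower genes 293 were, where 39.9 would be. Of the rest, 21 and 6 were called in the opposite direction. Genes are not independent replicates, and the exact p-values (6.1e-266 and 1.6e-189) treat them as such.

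Immediate-early genes, which growth factors and other stimuli induce within minutes, had a similar median T3 effect in both genotypes. In a list of 28 such genes, written after FOS and EGR1 had been seen, 26 were tested, 16 were called higher in WT and 6 in the knockout line, with 0 lower in either, and 1, EGR1, was called in the interaction (−1.46, adjusted p = 0.0371). EGR1 measured 17.4 ± 4.23 CPM in the knockout and 5.31 ± 1.75 in the WT controls, and 82.7 ± 8.52 and 69.4 ± 12.0 with T3. Its higher untreated level therefore enters that difference. The list median was 0.70 in WT and 0.68 in the knockout line, where leaving out each library gave 0.61 to 0.90. Over the 16 list genes raised in WT the slope of knockout on WT effects was 0.786, against 0.296 over all 1423 genes raised in WT, a difference of slopes that was not tested. The 20 list genes not called in the knockout line had a median of 0.59 there and all 20 were positive, but they belong to the same list, so a pattern made by picking genes on their own values is not excluded. It may also come from a T3 action that does not need THRB, or from handling or a medium change shared by the T3 cultures, and the labels do not tell these apart.

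Other splits of the same 6 libraries called 0 genes in each pairwise contrast, against 2707 for T3 in WT, 24 for T3 in the knockout line, and 1281 and 1811 for the knockout effect without and with T3, so the real split ranked 1 of 10 each time, and 10 splits are too few for a share under 0.05. Lists were less distinct. As many lists as the real 7 for T3 in WT came from 5 of 10 splits (highest other 11), as many as the real 10 for T3 in the knockout line from 6 (highest other 18), as many as the real 14 without T3 from 4 (highest other 19) and as many as the real 10 with T3 from 2 (highest other 11). For the interaction 59 of 100 splits gave at least the real 5 lists, up to 18, so chance is not excluded for that number of lists.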
